A study of Rattus norvegicus with 21 samples.

How the data were processed

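Messenger RNA was sequenced from immune cells sorted from the injured side of the brain of adult rats after transient occlusion of the middle cerebral artery (MCAO), a model of ischaemic stroke, or after a sham operation. Per the labels' protocols, cells were separated by flow cytometry into microglia (CD11b+ with low CD45), the resident macrophages of the brain, and blood-derived macrophages (CD11b+ with high CD45). Polyadenylated RNA was made into strand-specific libraries. The 21 libraries form 6 groups by title: MCAO microglia, MCAO macrophages and sham microglia, with 3 libraries per group in a set here called the 24h set and 4 per group in a set whose titles carry the prefix 7D. The labels call the replicates biological without saying which animals they came from, so p-values measure the spread between these libraries.

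Several label fields disagree. In the 24h set, the cell fraction field of microglia replicate 3 and macrophage replicate 3 is the opposite of their titles and source names; groups followed the titles and source names, and the other assignments were run as alternatives. All 12 libraries of the 7D set have a treatment field that reads 24 h, and the 4 titled MO have a source name and a cell fraction field of microglia. For these the titles were used as well, so neither the time after operation nor the gate of the 7D macrophages is settled by the labels. The sham libraries have a treatment field naming a PBS injection, while the protocol describes a sham operation.

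Reads were processed with bcl2fastq, TopHat2 and RSEM on genome build rn5, per the submitters' processing notes; versions and annotation release were not given in the sources used here. Each deposited file holds 1 library as RSEM expected counts, the estimated number of reads of each transcript. TPM and FPKM, which the authors deposited beside them per the file headers, were not used in any test because they are already scaled. The files list 30404 Ensembl transcript identifiers, followed by 2 lines named Chi3l1 and Nos2. In these 2 lines the values sit 2 columns to the right of the headers, so that the expected count stands under the FPKM header, and their effective lengths imply a slightly longer mean fragment than those of the transcripts in each library. They were read from the displaced columns as a separate quantification, and whether their reads are also counted in transcripts of the same genes is unknown. The values are per transcript, and RSEM divides reads that several isoforms or near-identical copies share, so a change of one transcript can be a change in that division. Between 22.2% and 24.2% of the transcripts detected in a library had an expected count that was not whole (tolerance 0.001).

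The files do not pair the transcript identifiers with gene names, and 0 of them were found in the table of 47357 rat genes used here (assembly GRCr8). Therefore the 26 gene lists (414 genes) fixed before the data were examined, and the rule for naming genes from them, could not be applied. The rule was to name, per comparison, the genes with the largest changes among those past the threshold with a mean log2 CPM of at least 3 and no overlap between groups. Without names it was applied to 24h microglia against sham only, for 2 identifiers that rose and 2 that fell, a limit set after the files were seen. Chi3l1 and Nos2 are reported throughout because they are the only named genes in the files. No coordinates are given by the files, so none are reported.

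Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM normalisation, filterByExpr with a minimum count of 10 and a minimum total of 15, one term per group). Comparisons within a set were fitted on the libraries of that set, leaving 13081 transcripts in the 24h set and 13384 in the 7D set. Differences between sets, as interaction contrasts, were fitted on all 21 libraries and 14252 transcripts. Library sizes and normalisation came from the transcripts, and Chi3l1 and Nos2 were added to each fit and adjusted with them. Adjusted p-values are Benjamini-Hochberg values, and a transcript is said to rise, fall or be called where this value was under 0.05. Levels are TMM-normalised CPM (counts scaled by the effective library size). For a level of 0, the limit is the CPM of 3 counts in each library, which covers counting error only.

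Whole libraries were compared on log2 CPM (prior count 1). Standard errors (SE) of edgeR log2 fold changes are approximate. Each was derived as the absolute log2 fold change divided by the square root of its F statistic. Root mean squares of log2 fold changes were corrected by subtracting the mean squared standard error. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom between replicates was 5.81 to 65.3. Same-numbered libraries of 7D microglia and 7D macrophages deviated together from their group means (r = 0.21 to 0.28 across transcripts in the 4 pairs, each highest with its own number), so these numbers were taken to pair the samples. The pairing comes from this correlation, not from the labels. In 24h microglia and macrophages the 3 correlations were lower, at 0.097 to 0.160, though each was also highest with its own number. These libraries were not taken as pairs. Sham libraries correlated best with their own number in 3 of 4 cases with 7D microglia, 2 of 4 with 7D macrophages and 1 of 3 in each 24h comparison. They were not taken as pairs either.

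On simulated counts drawn from the real means, 100 transcripts changed 2-fold and 100 changed 4-fold were recovered at 53% and 80% for 24h microglia against sham (13081 transcripts). For 7D macrophages against microglia (13384 transcripts) recovery was 60% and 83%, and for the microglia difference between sets (14252 transcripts) it was 36% and 68%. All other simulated transcripts had the same mean in every group, so a smaller share changed than was called in the real comparisons. The adjusted threshold depends on that share, so recovery in the reported tests can differ. The alternatives planned at the start were DESeq2 size factors, the DESeq2 Wald test (version 1.42.0), limma-voom with quality weights (version 3.58.1), no low-count filter, a replicate block, other sets of libraries in the fit, the alternative cell fraction labels and leaving out each library. Thinning to the smallest total, removing the trend with transcript length and keeping only transcripts with whole counts were added after seeing the data.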

Results

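Transcript levels were measured by strand-specific RNA sequencing in 21 libraries of sorted rat brain immune cells. MCAO blocks the artery that supplies much of the side of the brain and is then reversed to allow reperfusion. The 24h set held 3 libraries each of MCAO microglia, MCAO macrophages and sham microglia, and the 7D set held 4 of each. Total expected counts per library were 6923630 to 9668961 in the 24h set and 11115359 to 15401910 in the 7D set. Between 15836 and 17351 transcripts had an expected count above 0 in a library.

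Libraries were compared by principal components of their transcript levels. The first component (38.5% of variance) placed sham microglia at one end and 24h macrophages at the other, with group means of 91.8 ± 0.926 (SD, n = 3) for 24h sham, 75.0 ± 3.13 (n = 4) for 7D sham, and -118.0 ± 13.3 (n = 3) for 24h macrophages. MCAO microglia of both sets lay between, at -1.21 ± 19.1 (n = 3) and -1.94 ± 9.87 (n = 4), and 7D macrophages at -52.5 ± 8.34 (n = 4). The second component (14.7%) was lowest in 7D microglia, at -59.6 ± 4.07 (n = 4). Across transcripts, which are not independent replicates, the mean correlation of log2 CPM between macrophage and microglia libraries was 0.87 in the 24h set and 0.93 in the 7D set. Both sets of MCAO microglia correlated with each other at 0.94, above their correlations with the sham libraries of their own set (0.90 in each). On both components, the 24h libraries whose label fields disagree, microglia replicate 3 and macrophage replicate 3, lay with the groups of their titles.

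**Figure D1:**
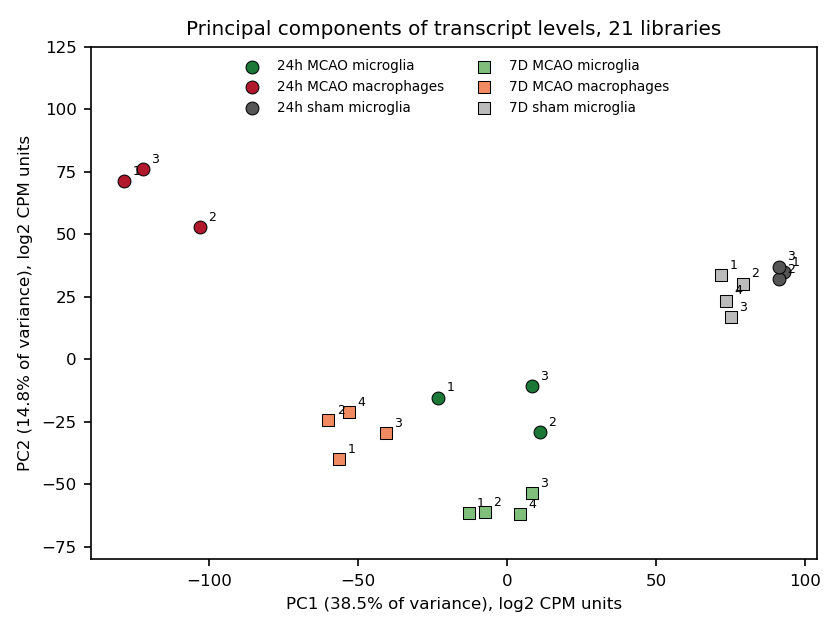
Each point is 1 of 21 libraries on the first 2 principal components of log2 CPM, coloured by group, with its replicate number. Sham microglia lie to the right (PC1 71.9 to 92.9), 24h macrophages to the left (-128.6 to -103.1), and MCAO microglia and 7D macrophages between them.

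The sets also differed apart from the injury. Sham microglia of the 7D set differed from those of the 24h set in 386 of 14252 transcripts (238 higher, 148 lower in 7D), and the mean fragment length implied by the files was 157 to 171 nt in the 24h set and 178 to 193 nt in the 7D set. Set and title time go together, so levels set side by side across the sets, as on the components and in the correlations above, carry both, and effects were compared between sets as differences of within-set contrasts.

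Microglia after MCAO in the 24h set were compared with sham microglia to show how resident cells differ after ischaemia. Of 13081 transcripts tested, 3246 rose and 2702 fell, of which 1317 rose and 781 fell at least 2-fold. Transcript ENSRNOT00000075989 was at 0 in all 3 sham libraries and at 19.9 ± 23.2 CPM (SD, n = 3) in MCAO microglia, of which replicate 1 held 45.9 and replicate 2 held 1.38 CPM, at least 51.3-fold higher (floor of 3 counts per library, edgeR adjusted p = 0.017). That limit rests on replicate 1 and is 17.7-fold without it, and 75.1-fold without replicate 2; in 24h macrophages it was at 55.8 ± 20.1 CPM (n = 3). ENSRNOT00000056933, also at 0 in the 3 sham libraries, was at 11.8 ± 6.29 CPM (n = 3), at least 30.6-fold higher (edgeR adjusted p = 0.00024), and at 21.6 ± 3.1 CPM in 24h macrophages (n = 3). Both were highest among the microglia in replicate 1. ENSRNOT00000061950 fell from 2575.4 ± 329.9 CPM in sham to 102 ± 81.0 CPM (n = 3 each), a log2 fold change of -4.66 ± 0.95 (SE, edgeR adjusted p = 0.0039). ENSRNOT00000075570 fell from 32.2 ± 11.8 CPM (190.7, 379.2 and 190.8 expected counts) to 0 in all 3 MCAO libraries (edgeR adjusted p = 0.024). Its counts come in steps, so no limit is given for the fold, and in 24h macrophages and in each 7D group some libraries were at 0 and others at 189.3 to 570 expected counts. The call of ENSRNOT00000075989 ended with limma-voom (adjusted p = 0.061, range over alternatives 1.9e-07 to 0.061), and that of ENSRNOT00000075570 ended in 5 of 16 alternatives, among them without microglia replicate 1 (adjusted p = 0.056) and without sham replicate 2 (adjusted p = 0.059, range over alternatives 0.0033 to 0.061).

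Chi3l1, which encodes a secreted chitinase-like glycoprotein, and Nos2, the inducible nitric oxide synthase, did not pass the threshold in this comparison. Chi3l1 was at 22.7 ± 23.0 CPM in 24h microglia and 14.8 ± 4.28 CPM in sham (n = 3 each, log2 fold change 0.61 ± 0.66, edgeR adjusted p = 0.47). For Nos2 the levels were 4.18 ± 4.55 and 1.76 ± 1.39 CPM (n = 3 each, log2 fold change 1.21 ± 1.00, edgeR adjusted p = 0.36). Both genes were highest in microglia replicate 1, with Chi3l1 at 48.9 CPM and Nos2 at 9.32 CPM, against 5.93 and 0.635 CPM in replicate 2. The direction of both rests on replicate 1, since without it the log2 fold changes were -0.67 for Chi3l1 and -0.20 for Nos2.

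Macrophages after MCAO in the 24h set were set against sham microglia, the only sham cells analysed here, so this comparison joins cell type and injury. Chi3l1 rose 8.4-fold, to 125.6 ± 39.4 CPM (n = 3, log2 fold change 3.07 ± 0.65, edgeR adjusted p = 0.0024). Nos2 rose 10.8-fold, to 20.0 ± 13.7 CPM (n = 3, log2 fold change 3.44 ± 0.98, edgeR adjusted p = 0.011). Across all transcripts 4757 were higher and 4378 lower in macrophages, of which 2635 and 2300 differed at least 2-fold. ENSRNOT00000061950 was at 13.5 ± 10.4 CPM in macrophages (n = 3), 191-fold lower (edgeR adjusted p = 0.00025). Without macrophage replicate 3 the log2 fold change was 2.84 for Nos2 and -8.28 for ENSRNOT00000061950, and without sham replicate 2 it was 4.18 for Nos2. The Nos2 call ended without both libraries whose label fields disagree (log2 fold change 2.83, adjusted p = 0.054, range over alternatives 0.00038 to 0.18). With groups taken from the cell fraction field, both calls ended, with adjusted p = 0.14 for Chi3l1 (range over alternatives 9.9e-05 to 0.14) and 0.18 for Nos2, and the number called was 4422.

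Macrophages and microglia sorted after MCAO were then compared directly in the 24h set. Chi3l1 was 5.48-fold higher in macrophages (log2 fold change 2.46 ± 0.62, edgeR adjusted p = 0.010), with the 3 macrophage libraries at 90.8 to 168.4 CPM, all above the microglia libraries. The Nos2 difference was 4.69-fold (log2 fold change 2.23 ± 0.88) and missed the threshold (edgeR adjusted p = 0.063), but passed it in 6 of 17 alternatives (adjusted p 0.016 to 1 over them all), among them DESeq2, limma-voom and leaving out microglia replicate 1 or macrophage replicate 2. Without microglia replicate 1 the log2 fold changes were 3.71 for Chi3l1 and 3.61 for Nos2, and without macrophage replicate 3 it was 1.63 for Nos2. In all, 3239 transcripts were higher in macrophages and 3143 higher in microglia, of which 1209 and 1434 differed at least 2-fold. Of the 3246 transcripts above sham in MCAO microglia, 1466 were higher still in macrophages and 476 were lower in macrophages than in microglia. Without the 2 libraries whose label fields disagree 4251 transcripts were called, and Chi3l1 was not (adjusted p = 0.11, range over alternatives 0.00033 to 1). When these 2 libraries exchanged groups, edgeR called 0 transcripts, with 123 at an unadjusted p under 0.05; no other tool was run on that grouping.

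**Figure D2:**
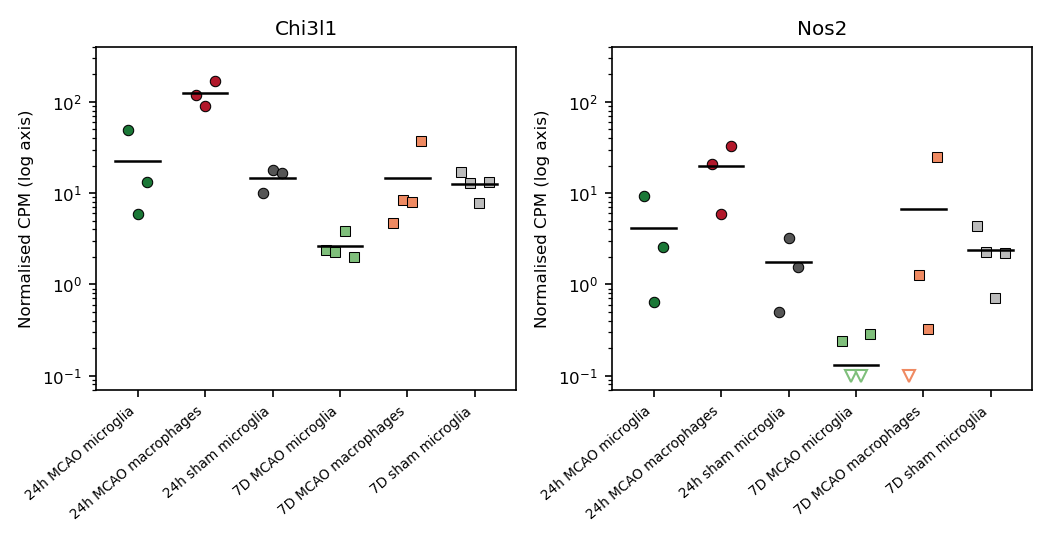
Normalised CPM of Chi3l1 and Nos2 in each library (points, log axis) with the group mean (line); circles are the 24h set, squares the 7D set, and open triangles mark libraries at 0. Chi3l1 was above 90 CPM in the 3 libraries of 24h macrophages only, and 1 library of 7D macrophages stood at 36.96 CPM for Chi3l1 and 25.1 CPM for Nos2.

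In the 7D set, MCAO microglia had less Chi3l1 than sham microglia. Its level was 2.62 ± 0.81 CPM against 12.7 ± 3.77 CPM (n = 4 each), 4.94-fold lower (log2 fold change -2.30 ± 0.58, edgeR adjusted p = 0.0067), and each MCAO library lay below each sham library. Nos2 was at 0 in 2 of the 4 microglia libraries and at 0.240 and 0.284 CPM in the others, against 2.37 ± 1.49 CPM in sham (log2 fold change -4.05 ± 1.69, edgeR adjusted p = 0.069, and -4.71 without microglia replicate 4), and the limit for a library at 0 was up to 0.271 CPM. Nos2 passed the threshold in 3 of 17 alternatives, which were DESeq2 (adjusted p = 0.035), the replicate block (0.028) and all 21 libraries in the fit (0.049, range over alternatives 0.028 to 0.14). Among 13384 transcripts, 3070 rose and 3110 fell, of which 1034 and 1290 changed at least 2-fold. ENSRNOT00000075989 rose to 13.8 ± 7.81 CPM from 0.212 ± 0.425 CPM (n = 4 each, log2 fold change 6.01 ± 0.85, edgeR adjusted p = 0.00015); its size rests on sham replicate 4 (0.850 CPM), as the other 3 sham libraries were at 0. ENSRNOT00000056933 rose 6.85-fold, to 11.5 ± 3.51 CPM (n = 4, edgeR adjusted p = 0.0022). ENSRNOT00000061950 fell from 1440.7 ± 1110.3 CPM to 3.78 ± 1.24 CPM (n = 4 each, log2 fold change -8.59 ± 0.92, edgeR adjusted p = 2.0e-05).

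Macrophages of the 7D set differed from sham microglia in 7573 transcripts, 3807 of them higher and 3766 lower, with 1647 and 1466 differing at least 2-fold. Mean Chi3l1 was 14.5 ± 15 CPM in macrophages and 12.7 ± 3.77 CPM in sham (n = 4 each, log2 fold change 0.16 ± 0.53, edgeR adjusted p = 0.82). This mean rested on replicate 4, at 36.96 CPM against 4.71 to 8.35 CPM in replicates 1 to 3; without it Chi3l1 was lower in macrophages than in sham (log2 fold change -0.84, adjusted p = 0.041, range over alternatives 0.041 to 0.97). Nos2 was likewise at 25.1 CPM in replicate 4 and at 0 to 1.26 CPM in replicates 1 to 3 (group log2 fold change 1.45 ± 1.25, edgeR adjusted p = 0.35, and -2.08 without replicate 4). ENSRNOT00000061950 was 308-fold lower in macrophages, at 4.71 ± 4.2 CPM (n = 4, log2 fold change -8.27, edgeR adjusted p = 1.4e-05, and -9.04 without replicate 4).

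The comparison of macrophages with microglia in the 7D set gave the fewest calls of the within-set comparisons, with 871 transcripts higher and 600 lower in macrophages. The larger differences were mostly toward macrophages, since 489 transcripts were at least 2-fold higher and 78 at least 2-fold lower. Chi3l1 was 5.51-fold higher in macrophages (log2 fold change 2.46 ± 0.58, edgeR adjusted p = 0.019), with each macrophage library above each microglia library. Nos2 had a log2 fold change of 5.50 ± 1.69 and missed the threshold (edgeR adjusted p = 0.058), but passed it in 5 of 17 alternatives (adjusted p 0.011 to 0.40 over them all), among them DESeq2 and leaving out macrophage replicate 1 or 3. Without macrophage replicate 4 the log2 fold changes were 1.44 for Chi3l1, still past the threshold, and 1.95 for Nos2, and without microglia replicate 4 it was 6.17 for Nos2. The Chi3l1 call ended without microglia replicate 1, 2 or 4 (adjusted p = 0.055, 0.054 and 0.065) and with limma-voom (adjusted p = 0.060, range over alternatives 0.00017 to 0.065). Fewer transcripts were called without microglia replicate 4 (844) or macrophage replicate 2 (847), and limma-voom called 2658. Without sham replicate 3, which enters this comparison only through the shared fit, 2409 were called. The 600 lower calls were the less stable part, at 375 and 275 without microglia replicate 1 or 4, and 282, 257, 396 and 340 without macrophage replicates 1 to 4, while the 871 higher ones were 569 at the lowest, without microglia replicate 4.

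**Figure D3:**
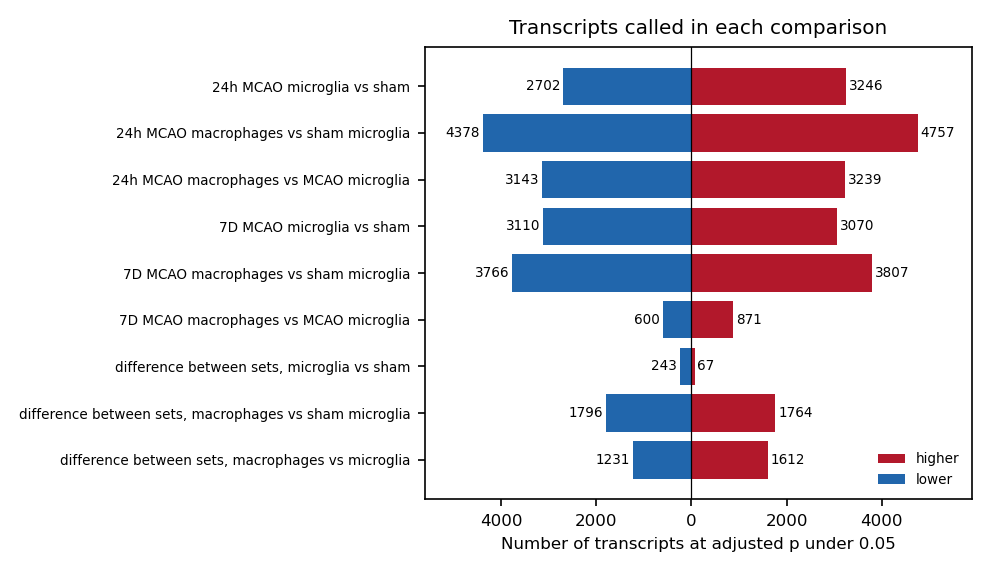
Number of transcripts at an edgeR adjusted p under 0.05 in each comparison, with those higher in the first-named group to the right and those lower to the left; for the differences between sets, right means higher in the 7D set. The 7D comparison of macrophages with microglia has 871 and 600 transcripts, against 3239 and 3143 in the 24h set.

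Changes of microglia against sham were largely shared by the sets, which have no library in common. Of 12789 transcripts tested in both, 2274 rose in both and 1832 fell in both, where independent lists would share 751.5 and 624.8, and 49 were called in opposite directions, where 1375.9 would be by chance. The correlation of log2 fold changes was 0.69 across transcripts, and their error-corrected root mean square was 1.03 in the 24h set and 1.00 in the 7D set. The interaction test found 310 transcripts whose change differed, 67 more positive and 243 more negative in the 7D set. For Chi3l1 the difference in log2 fold change was -2.91 ± 0.95 (edgeR adjusted p = 0.12) and for Nos2 -5.23 ± 2.17 (edgeR adjusted p = 0.25). The number of differing transcripts was 206 without 24h microglia replicate 1, 199 without 24h sham replicate 1 and 648 without 7D sham replicate 3. The excess of negative differences rests on that last library, since without it 310 were more positive and 338 more negative. DESeq2 called Chi3l1 (adjusted p = 0.028, range over alternatives 0.028 to 0.43). For Chi3l1 and Nos2 the differences were -1.64 and -3.84 without 24h microglia replicate 1. Over all alternatives they ranged from -4.61 to -1.64 for Chi3l1 and from -7.00 to -3.84 for Nos2. DESeq2 called 688 and limma-voom 786, with 41.9% more positive against 21.6% by edgeR.

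For macrophages against sham microglia the log2 fold changes of 3560 transcripts differed, 1764 more positive and 1796 more negative in the 7D set. The root mean square log2 fold change was 1.79 in the 24h set and 1.16 in the 7D set. Chi3l1 was among them, with a difference of -2.88 ± 0.89 (edgeR adjusted p = 0.023), and of -3.86 without 7D macrophage replicate 4. That call ended without 24h macrophage replicate 3 (adjusted p = 0.060), without 24h sham replicate 1 (adjusted p = 0.062), without both libraries whose label fields disagree (adjusted p = 0.064) and with groups from the cell fraction field (adjusted p = 0.50, range over alternatives 0.00088 to 0.50). Nos2 differed by -1.96 ± 1.77 (edgeR adjusted p = 0.47), by -5.48 without 7D macrophage replicate 4 (adjusted p = 0.010) and by -4.98 with limma-voom (adjusted p = 0.039, range over alternatives 0.010 to 0.89). The calls shared in direction were 3114 higher and 2989 lower, where independent lists would share 1334.5 and 1235.2, and 169 were in opposite directions, where 2568.3 would be by chance. The correlation of log2 fold changes was 0.77, above that of microglia, so the sets shared the directions in which macrophages differed from sham microglia, while the sizes differed. This contrast joins cell type and injury, so the shared directions cannot be assigned to a response of macrophages.

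Between macrophages and microglia, 2843 transcripts had a different contrast in the 2 sets, 1612 of them more positive and 1231 more negative in 7D. Here the root mean square log2 difference was 1.26 in the 24h set and 0.75 in the 7D set. Of 3119 transcripts lower in 24h macrophages than in microglia, 360 were also lower in 7D, and of 3115 higher, 714 were also higher in 7D (145 and 206 by chance). The 360 were 190, 176 and 217 without 7D macrophage replicate 1, 2 or 4 and 200 without 7D microglia replicate 4, and the 1231 were 815 without 24h microglia replicate 2. The interaction was toward a smaller contrast in 7D for 1478 of the former and 1073 of the latter, counts taken among transcripts called on the same 24h libraries, which favours a smaller value in the other set. For Chi3l1 the sets did not differ past the threshold (difference 0.03 ± 0.79, edgeR adjusted p = 1.00), but the value rests on single libraries, being -1.24 without 24h microglia replicate 1, -0.99 without 7D macrophage replicate 4 and -0.86 with limma-voom. Nos2 differed by 3.264 ± 2.075 (edgeR adjusted p = 0.31), with values of -0.28 to 6.07 over the alternatives. With the 24h groups taken from the cell fraction field, edgeR called 0 transcripts for the interaction of macrophages against microglia (819 at an unadjusted p under 0.05) and 18 for that of macrophages against sham.

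**Figure D4:**
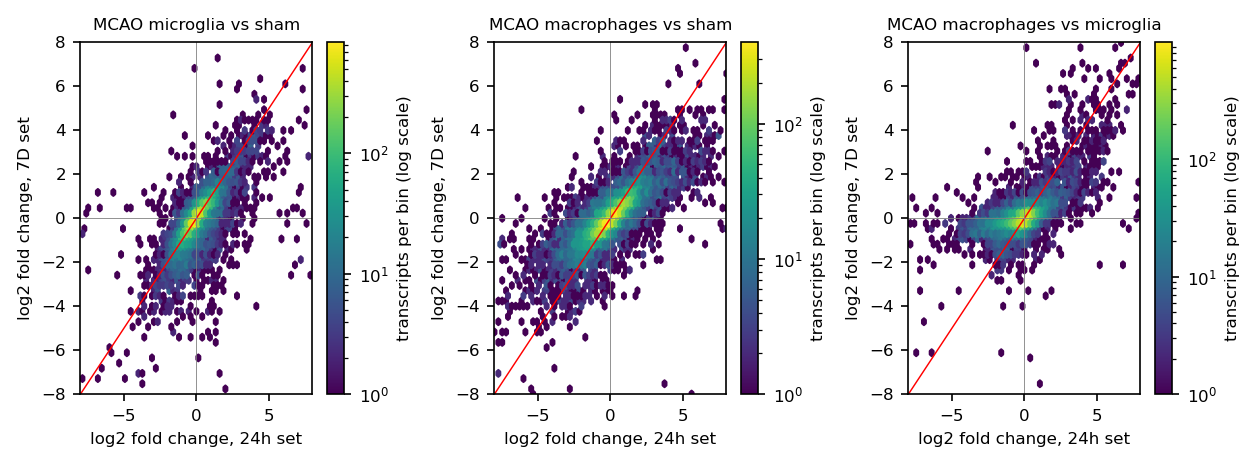
Density of transcripts by log2 fold change in the 24h set (horizontal) and the 7D set (vertical) for the 3 contrasts, with the line of equal change in red; transcripts beyond the axis limits are not drawn. The microglia contrast lies along the line (r = 0.69), and the contrast of macrophages with microglia has r = 0.63.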

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

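The tests of explanations below were set before their results were seen, after the patterns had been noticed; thinning, the removal of the length trend and the macrophage share over 8 to 31 transcripts were tests chosen after seeing the data, the last after its result was seen.

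In 42 tests, each of 1 measure in 1 group of 4 libraries of the 7D set, 7 had 1 library apart by more than the Dixon limit. Independent tests would give about 1 in 20 by chance (2.1 here). These tests share the same 12 libraries and related measures, so that number is only a rough guide. Mean fragment length was 178.3 nt in 7D sham replicate 2 and 188.1 to 189 nt in the others. In 7D sham replicate 3 the mean correlation with its own group was 0.9334, against 0.9489 to 0.9507. The second principal component of 7D microglia replicate 3 was -53.5, against -62.1 to -61.2. The most abundant transcript took 1.70% of the counts in 7D macrophage replicate 1 and 2.08% to 2.13% in the others. ENSRNOT00000075989 was at 0.850 CPM in 7D sham replicate 4 and at 0 in the other 3, where any level above 0 would pass the limit.

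Differences between the sets past the test's threshold were found for 310 transcripts in microglia against sham, 3560 in macrophages against sham and 2843 in macrophages against microglia. Of single items, Chi3l1 (edgeR adjusted p = 0.023) and ENSRNOT00000056933 (edgeR adjusted p = 0.0078) differed between sets in macrophages against sham. The call of ENSRNOT00000056933 ended with limma-voom and with groups from the cell fraction field (adjusted p = 0.16 in each, range over alternatives 5.2e-05 to 0.16), and it was at 0 in all 24h sham libraries, so its fold difference has no defined size. In each of these 3 tests, 2 of 60 splits of the libraries, the real one included, gave as many calls; the draws did not keep paired 7D libraries together. The highest other splits gave 2153, 4762 and 5482, and the next gave 40, 23 and 18. In each, the highest other split kept the sets of one cell type and exchanged those of the other but for 1 library, so it compares the sets themselves and points to a structure of the samples by set.

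The 5948 calls between 24h MCAO microglia and sham microglia were weighed against macrophages carried over into the microglia gate. A mixture of sham-type microglia and 24h macrophages lies between its parts, but 14.7% of the 3246 risen transcripts were also above the macrophages, which argues against it for these. Over 211 transcripts at least 20 times higher in macrophages than in sham, the median share of the macrophage level in microglia was 9.23%, 2.19% and 4.83% in replicates 1 to 3, with a 10th percentile at most 0.089 of the median, but sham levels of up to 5% enter there and are as large as the shares of replicates 2 and 3. Over the 8 to 31 transcripts with sham levels up to 0.877% (4 pairs of limits), the 10th percentile was 0.0019 to 0.251 of the median in the 3 libraries, which argues against one common share from cells like the sorted macrophages as the source of these levels, while carry-over as an addition, highest in replicate 1, stays open. Thinning left 5809 calls and removal of the trend with transcript length 5755, so neither depth nor transcript length accounts for the difference. Mean fragment length was 168.5 to 170.8 nt in the 24h sham libraries and 159.2 to 163.3 nt in the 24h MCAO microglia libraries. No test separated this difference in fragment length from the injury. The 10 splits were too few to judge chance (highest other 0, at most 382 at an unadjusted p under 0.05). Calls shared with the 7D set, which has no library in common, argue against chance for those transcripts. They were 2274 risen and 1832 fallen, where independent lists would share 751.5 and 624.8, and 49 were opposite, where 1375.9 would be by chance. An effect of ischaemia remains a hypothesis.

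Nos2 at 25.1 CPM and Chi3l1 at 36.96 CPM were apart in 7D macrophage replicate 4 from replicates 1 to 3 (0 to 1.26 and 4.71 to 8.35 CPM). Over 71 transcripts at least 8 times higher in 24h macrophages than in the other 3 libraries of 7D macrophages, replicate 4 held in excess a median of 6.71% of the 24h level, with a 90th percentile of 34.0%, against 25.2% for Chi3l1 and 126.4% for Nos2. The same medians for replicates 1 to 3, each over its own 43 to 69 transcripts, were -1.82%, 3.30% and -3.97%, with 90th percentiles of 3.50%, 11.9% and -0.048%. The median is low for an admixture of 24h-type macrophages. The upper range reaches the Chi3l1 share but not the Nos2 share, for which the 24h macrophage libraries ranged from 5.84 to 33.3 CPM. Levels of both sets enter this test along with the difference between sets, so an admixture cannot be told apart. As for a difference of the whole library, replicate 4 stood above its group by more than the Dixon limit for 161 transcripts. Replicates 1 to 3 did so for 106, 91 and 154, which decides nothing. A difference between the animals behind the libraries could also give this and was not tested.

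Macrophages and microglia differed less in the 7D set than in the 24h set. Leaving out each library, the corrected root mean square log2 difference was 1.24 to 1.41 in the 24h set and at most 0.792 in the 7D set. The correction takes out the approximate error of the fold changes, so this argues against a greater spread as the reason. It was not recomputed at equal depth. With every library thinned to the smallest total, 6120 transcripts were called in the 24h set and 1196 in the 7D set, so depth does not account for the fewer calls. The real split of the 7D libraries titled MO and Mg gave 1471 calls (844 at the lowest when leaving out each library), where other splits gave at most 10. This argues against the same cells under both titles, although the 8 splits that part the pairs are too few to exclude chance. It does not tell which gate the cells titled MO came from. A mixture of 24h-type macrophages with 7D microglia cannot be told apart from a change of the macrophages, since 6.46% of the called transcripts lay beyond both parts, but 4.90% (under the 5% allowed) without 24h macrophage replicate 3. The 489 transcripts at least 2-fold higher against 78 lower go with such a mixture, and time after ischaemia and set stay open and are not separable here. Which cells each gate held in either set could not be checked with markers, since no transcript was matched to a gene name.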

How the results depend on the processing

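Thinning, removal of the length trend and whole-count transcripts were tests chosen after seeing the data. Of 177 recalculated counts of called transcripts, 161 stayed within 1.5 times the reported one. With the 24h groups taken from the cell fraction field, the counts were 3567, 4422 and 0 for 24h microglia against sham, macrophages against sham and macrophages against microglia, and 86, 18 and 0 for the same contrasts between sets. The 0 values had 123 and 819 transcripts at an unadjusted p under 0.05 by edgeR. Without both libraries whose fields disagree, 4251 (main 6382) and 1634 (main 2843) were called for macrophages against microglia in the 24h set and between sets, with fewer libraries. For 7D macrophages against microglia limma-voom called 2658 (main 1471), and for the microglia difference between sets DESeq2 called 688 and limma-voom 786 (main 310); the cause was not tested. Leaving out 1 library at a time gave, for 24h microglia against sham, macrophages against sham and macrophages against microglia, 4731 to 5629, 8522 to 9021 and 5001 to 6369. The same contrasts gave 5239 to 7022, 6914 to 8216 and 844 to 1381 in the 7D set, and 199 to 648, 2828 to 3969 and 2023 to 3170 between sets. Only libraries of the groups compared were left out for these ranges. Without 7D sham replicate 3, which shares the fit, 2409 transcripts were called for 7D macrophages against microglia (main 1471). That count lies outside the range above and is not among the 177. Chi3l1 in 7D macrophages against sham changed from a log2 fold change of 0.16 to -0.84 without macrophage replicate 4, which then passed the threshold; leaving out each library gave -0.84 to 0.50. Of 597 recalculations for single genes, transcripts and shared calls, 552 were unchanged, 21 weaker, 17 stronger and 1 reversed. The other 6 were shared counts moved by over 1.5 times. Unchanged means the same side of the threshold for a gene or transcript, and within 1.5 times for a shared count. A change of sign with neither value past the threshold counted as unchanged, as for Chi3l1 and Nos2 in 24h microglia against sham without microglia replicate 1.

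The replicate block gave 2027 calls (main 1471) for 7D macrophages against microglia, whose numbers pair the samples, 6617 and 7941 for the 7D comparisons with sham, and 449 (main 310) for the microglia difference between sets. Among the calls of Chi3l1, Nos2 and the 4 transcripts in the comparisons where they are reported, it changed only that of Nos2 in 7D microglia against sham, which passed the threshold (adjusted p = 0.028, range over alternatives 0.028 to 0.14). In the 24h set, where the numbers were not taken to pair the samples, each microglia library still correlated best with the macrophage library of its number. The block there gave 5892, 9074 and 6246 calls. Gene list tests and their alternatives were not run because no transcript was matched to a gene name.

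In each 24h comparison the 10 splits of 6 libraries are too few to exclude chance; beside real counts of 5948, 9135 and 6382, the highest others were 0, 0 and 2. In the 7D comparisons with sham 1 of 35 splits, the real one, gave as many calls, and beside 6180 and 7573 the highest others were 396 and 0. That share is under 0.05 and the smallest these splits can give. Several comparisons were tested and the splits treat the libraries as exchangeable, so chance is made unlikely but not excluded. For 7D macrophages against microglia the 8 splits that part all 4 pairs are too few to exclude chance; beside 1471 the highest other was 1, and the 27 that keep a pair together gave at most 10. The split with 396 exchanged sham replicate 3 with a microglia library. Depth limits low transcripts most, since 3 counts correspond to 0.204 to 0.402 CPM.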

Other observations

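The values below were singled out after they had been seen.

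Sham microglia replicate 3 of the 7D set lay apart from the other 3 sham libraries. On the fourth principal component it was at -69.7, against 25.7 to 30.7, while on the first, which parts sham from MCAO libraries, it was among them (75.1, against 71.9 to 79.2). By more than the Dixon limit, it stood above the rest of its group for 714 transcripts and below it for 418. These were 8.46% of 13376, against 0.763% to 2.44% for the other libraries of the 7D set. Its Chi3l1 (7.78 CPM) and Nos2 (0.705 CPM) were the lowest of the 4 sham libraries; in 7D MCAO microglia Chi3l1 fell, and Nos2 was lower, passing the threshold in 3 of 17 alternatives and not by the test used. ENSRNOT00000061950, which fell in MCAO microglia of both sets, was at 202.0 CPM in this library and at 804.1 to 2396.3 CPM in the other 7D sham libraries. Measured against another sham library, its displacement along the difference of 7D microglia from the remaining sham libraries was 0.168 of that difference (range 0.111 to 0.196 over 3 reference libraries), against -0.093 to 0.017 for the others; its correlation with that difference was 0.176, so little of its departure lies along it. Without it, 7022 transcripts were called for 7D microglia against sham, beside 6180 with it. For 7D macrophages against microglia, 2409 were called without it and 1471 with it.

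In 24h macrophages, Chi3l1 and Nos2 were both lowest in replicate 2 (90.8 and 5.84 CPM) and both highest in replicate 3 (168.4 and 33.3 CPM), and in 24h microglia both were highest in replicate 1.

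The expected counts of ENSRNOT00000075570 took few values across the 21 libraries. They were 0 in 11 libraries, 189.3 to 190.8 in 6, 379.1 and 379.2 in 2, and 508.5 and 570 in the other 2, while library totals ranged from 6923630 to 15401910.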
